A study of Mus musculus with 38 samples.

How the data were processed

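DNA methylation was measured by RRBS in 29 mouse liver libraries and expression by RNA sequencing in 9 pools of livers. For RRBS, the deposited site files give, per the file headers, counts of methylated and of all reads at each cytosine position, on mm9 coordinates. The same deposited files give the methylated fraction, which the authors computed as the former count over the latter, rounded to 3 decimals. For RNA, the authors deposited FPKM values per gene from Cufflinks after alignment with TopHat, with lower and upper 95% bounds and a status, and no read counts. Versions of TopHat and Cufflinks are not given. The design notes state that RNA from several livers was pooled, so each pool is 1 library and no check between replicates is possible for expression. Gene positions in the expression files of the diet set do not end where those of mm9 do, so no positions were taken from them.

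The counts of both strands of a CpG were summed and sites on autosomes were kept. Reads were then summed over tiles of 1 kb. A tile was tested when it had at least 20 reads and 2 sites in every library of its set, the diet set or the age set. Tests used R 4.3.3 with edgeR 4.0.16, with a quasi-likelihood fit of methylated and unmethylated counts, and two-sided p adjusted by the Benjamini-Hochberg method over all tiles of a comparison. A tile was called at an adjusted p under 0.05 and a difference of at least 10 percentage points. For the age trend this difference was the fitted slope times the age range. The means at 4 and 25 months of a tile called in the trend can therefore differ by less. There were 10 comparisons: diet in sedentary and in running mice, running on chow and on fast food, diet and running together, both averages, their interaction, 25 against 4 months, and a linear trend over age. Tiles were linked to genes by the annotation in the site files, which covers gene bodies and up to 5 kb upstream. That differs from the planned reach, since the files list no gene for sites downstream. The fit was tested on simulated data in which 200 tiles were changed.

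Mean methylation was the mean level of CpG sites with at least 10 reads in every library of a set. Diet and running were compared by an exact permutation test over 400 relabelings within the other factor, and age by Pearson's r and Spearman's rho with 100000 permutations. Together with the same tests in and outside CpG islands these made a family of 9. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, version 1.17.8 of the R package data.table, and matplotlib 3.10.9 for figures.

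Expression was compared as the log2 ratio of FPKM plus a pseudocount of 1 for genes with at least 1 FPKM in either pool and a usable status in both. An absolute log2 ratio of at least 1 was counted, with the number whose bounds did not overlap, and no p was computed. The median ratio of each of 30 gene lists was ranked among 10000 random lists of genes matched on expression. These lists, the groups, the comparisons and most other settings to be tried were fixed before the data were examined. Of 551 genes in the lists, 515 were in the site annotation. Hox genes had at most 2 members measured in the pools, so that list has no median.

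Genes named in the text follow a rule. For expression, the 10 highest and 10 lowest ratios among genes with at least 5 FPKM in either pool were eligible, apart from predicted, microRNA, small nucleolar and mitochondrial genes, with up to 4 genes of largest absolute ratio from each list and the DNA methylation machinery throughout. For methylation, up to 10 called gene-linked tiles in each direction were eligible, by size between 25 and 4 months among tiles whose groups did not overlap and by adjusted p in the trend, with up to 4 called tiles per list. Imprinted tiles with a mean of 30% to 70% served as a level check. Other genes are said to be chosen after their values were seen. These include the diet tiles with the smallest p, genes that passed only when adjusted over the list alone, which was computed last, and genes of the 9, 12 and 18 month pools. Marker lists of 5 other tissues or states (adrenal gland, skeletal muscle, fat tissue, fetal liver and squamous epithelium) were written after the pools had been compared and before those markers were tested.

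The single libraries were set against the range of the 14 age libraries, counting tiles at least 25 points outside it, with Wilson 95% intervals for levels that are named. Lists among called tiles were tested with Fisher's exact test over gene-linked tiles. Methylation and expression differences were related across genes by Spearman's rho with 100000 permutations. Calls were compared between sets against 10000 random tile sets matched on mean level and direction.

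Alternatives tried for tiles were limma 3.58.1 on log ratios, at least 10 or 50 reads, tiles of 500 bp, no minimum difference or one of 20 points, only the groups compared, coverage thinned to the lowest library, the X chromosome included, a replicate block, and each library left out in turn. Mean methylation was repeated at 5 and 20 reads per site, with reads pooled, with a replicate block and without each library. Expression was repeated with a pseudocount of 0.1, no filter, a filter of 5 FPKM and ratios centred on their median. Leaving out variant sites, using sites covered in every library, leaving out libraries that stood apart, and the split by islands were added after seeing the data. Genes without a usable FPKM status were left out of ratios.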

Results

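DNA methylation and gene expression were measured in mouse liver under a chow or fast food diet, with or without a running wheel, and across age. Methylation came from reduced representation bisulfite sequencing (RRBS), which reads CpG sites in CpG-rich fragments of the genome, in 29 libraries. Expression came from RNA sequencing of pooled livers in 9 pools. The diet set held 3 RRBS libraries in each of 4 groups of male mice of mixed 129, C57BL/6 and FVB background: chow and sedentary (NCC), chow and running (NCE), fast food and sedentary (FFC), and fast food and running (FFE). These mice were 12 months old at the end of the intervention. The age set held C57BL/6 livers at 4, 9, 12 and 18 months with 3 RRBS libraries each, and at 25 months with 2. Livers of a beta-catenin transgenic mouse, of such a mouse given DEN, and of a mouse given DEN had 1 RRBS library each. Each group of the diet and age sets also had 1 RNA pool, so expression had no replicates and its differences carry no test. The labels do not say whether replicate libraries came from separate animals apart from the design text, which speaks of replicates, so p-values measure the spread between these libraries.

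Depth varied most in the diet set. Its libraries held from 291381 CpG sites and 3877081 CpG reads in FFE replicate 2 to 1219630 sites and 58006284 reads in FFC replicate 1. Age libraries held from 613023 to 848699 sites, and their reads ran from 13383024 in 9MO replicate 1 to 133390457 in 25MO replicate 2. The 3 single libraries held from 40743143 to 72346268 CpG reads. The lowest coverage listed for any site was 5 reads. RNA pools held FPKM of at least 1 in 11146 to 11874 genes, and their read depth is unknown.

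Whether the fast food diet or running altered liver methylation as a whole was asked first. Fast food livers had a lower mean methylation level than chow livers, by a difference of -0.597 percentage points averaged over sedentary and running mice. Over 28688 CpG sites the level was 24.1% ± 0.153 in NCC, 23.9% ± 0.161 in NCE, 23.6% ± 0.234 in FFC and 23.2% ± 0.402 in FFE (SD, n = 3 each). The difference was larger at sites outside CpG islands, at -0.975 points from a level near 48.2% in NCC, than in the largely unmethylated islands, at -0.272 points from 3.35%. The exact permutation test within exercise groups, two-sided, gave p = 0.005 for diet, the smallest of its 400 relabelings, and an adjusted p of 0.0113 over 9 relations. For running the difference was -0.315 points, with an exact permutation p of 0.05 and an adjusted p of 0.0643, so it did not hold up. It passed an unadjusted p of 0.05 at 20 reads per site (-0.411 points, exact permutation p = 0.015), with the reads of all sites pooled (-3.80 points, exact permutation p = 0.03) and without NCC replicate 2 (-0.349), NCE replicate 2 (-0.346), FFC replicate 2 (-0.381) or FFE replicate 1 (-0.391). Pooling the reads of all sites, which weights sites by depth, gave -2.32 points for diet with an exact permutation p of 0.23.

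**Figure D1:**
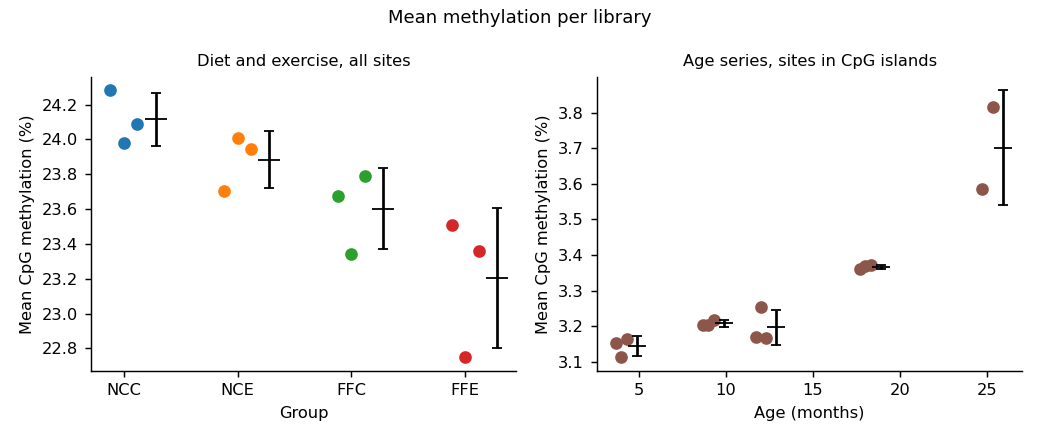
Mean CpG methylation in percent per library (points), with the group mean and SD (bars), by diet and exercise group over all sites (left) and by age in months over sites in CpG islands (right); the vertical axes do not start at 0. Group means go from 24.1% in NCC to 23.2% in FFE, and from 3.14% at 4 months to 3.70% at 25 months.

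Whether single regions differed by diet or running was asked of 18328 tiles of 1 kb, each with at least 20 reads in all 12 libraries. No tile passed the test in any of the 8 comparisons, so no gene region was called as changed by diet, by running, by both together or by their interaction. Cux2, a transcription factor of the female liver and a member of the fixed female-biased list, gave the smallest p for diet averaged over exercise. Its intronic tile (mm9 chromosome 5, 122475001 to 122476000) held 1.3% ± 1.3 in NCC, 13.9% ± 6.1 in NCE, 39.5% ± 19 in FFC and 41.0% ± 9.7 in FFE (SD, n = 3 each), at an adjusted p of 0.834 by edgeR for that comparison. Nr4a3, a nuclear receptor, chosen like Cux2 after its values were seen, had an upstream tile (chromosome 4, 48061001 to 48062000) that differed by 13.5 points for diet at an adjusted p of 0.969. edgeR gave 824 tiles at an unadjusted p under 0.05 for diet in sedentary mice, 464 for diet in running mice, 804 for running on chow, 355 for running on fast food, 964 for diet and running together, 806 for diet averaged over running, 611 for running averaged over diet and 675 for the interaction. With no difference at all, a share of 0.05 of the 18328 tiles would pass, so these counts alone are no evidence of differences. limma also called 0 tiles in all 8. The comparison had little power, since of 100 tiles simulated at 40 points edgeR recovered 1 between 3 and 3 libraries and 74 for diet averaged over exercise, and of 100 at 20 points it recovered 0 and 1. Without NCC replicate 1, which left 2 libraries in that group, 13 tiles were called for diet in sedentary mice, 10 for running on chow, 20 for diet and running together and 2 for running averaged over diet.

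Adjusted over the list alone, and not across the lists or comparisons, 3 genes of the fixed lists had a tile past the threshold for diet averaged over exercise by edgeR. These were Cux2 (adjusted p = 0.0025 over 9 tiles), the drug oxidase Cyp1a2 (adjusted p = 0.0195 over 3 tiles) and Bhmt, which remethylates homocysteine (adjusted p = 0.0269 over 15 tiles). An exonic tile of Cyp1a2 (chromosome 9, 57529001 to 57530000) held 38.4% ± 7.9 in NCC, 50.5% ± 3.6 in NCE, 68.4% ± 11.9 in FFC and 65.7% ± 5.3 in FFE (SD, n = 3 each). An upstream tile of Bhmt (chromosome 13, 94407001 to 94408000) held 2.4% ± 4.1, 5.1% ± 6.2, 27.4% ± 5.3 and 22.4% ± 5.6 in the same order, with as few as 20 reads in a library. Over all tiles the adjusted p of Cyp1a2 and Bhmt was 1.0. For diet in sedentary mice Cux2 and Cyp1a2 passed over their lists, for diet and running together Cux2 did, and in the other 5 comparisons 0 tiles did.

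Tiles of imprinted genes, methylated on 1 parental copy and so expected near the middle of the scale, served as a level check. In the diet set 9 such tiles, among them tiles of Gnas, ranged from 0.0% to 92.5% across libraries, with a median range of 62.2 points per tile. In the age set 37 such tiles ranged from 13.6% to 84.3%, with a median range of 20.6 points. In the diet set their SD was 29.4 points in NCC replicate 3, 27.2 in NCE replicate 2, 22.3 in FFC replicate 3 and 20.1 in FFE replicate 2, against 6.86 to 19.2 in the other 8 libraries. Duplicate reads cannot be counted in the site files, so whether fewer molecules stood behind the tile levels of these 4 libraries is unknown. Across all tested tiles the SD within groups averaged 4.78 points in the diet set and 3.07 in the age set.

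The effect of fast food on expression in sedentary livers was read from the FFC and NCC pools. Genes of lipid storage and fat synthesis were higher on fast food and genes of cholesterol synthesis were lower. All 16 measured genes of lipid droplets and lipid uptake had a positive log2 ratio, with a median of 0.89, and 18 of 20 genes of fatty acid and triglyceride synthesis did, with a median of 0.72. The fatty acid carrier Fabp4 (ENSMUSG00000062515) stood at 160 against 21 FPKM, the fatty acid transporter Cd36 at 69.3 against 10.9, and the droplet protein Cidec at 10.7 against 0.726. The elongases Elovl5 and Elovl6 stood at 468 against 143 and at 51.6 against 18.2 FPKM, and fatty acid synthase (Fasn) at 148 against 61.7. Of 24 genes of cholesterol synthesis and uptake, 21 had a negative ratio, with a median of -0.64. Among them squalene epoxidase (Sqle) stood at 6.00 against 21.9 FPKM, and Idi1, which makes an isoprenoid unit of cholesterol, at 26.0 against 82.1.

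Other lists differed between the same pools. Genes of fatty acid oxidation had a median of 0.24, with 22 of 25 positive, including the starvation hormone Fgf21 at 4.05 against 0.411 FPKM. Cytokines and chemokines had a median of 0.55 and macrophage markers 0.26, and the T cell attractant Cxcl9 stood at 9.47 against 3.43 FPKM. The acute phase genes Saa1 and Lcn2 stood at 483 against 37.6 and at 37.6 against 4.25 FPKM, though the whole list had a median of 0.17. Xenobiotic genes had a median of -0.51, with Cyp3a11, a major drug oxidase, at 1045 against 2593 FPKM. Male-biased liver genes had a median of -0.39 and female-biased genes 0.80, with the pheromone carrier Mup1 at 506 against 1044, Selenbp2 at 77.0 against 469 and Cyp2b9 at 24.2 against 5.74 FPKM. Each of these medians lay at percentile 100 or 0.0 among 10000 lists of genes matched on expression. In all, 335 of 11634 genes had an absolute log2 ratio of at least 1, 213 higher and 122 lower, and in 128 of them the authors' 95% bounds did not overlap. Scd1, a desaturase of the lipogenic list, had no usable estimate in this comparison.

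Markers of fat and muscle moved with the lipid genes. Of 8 measured adipocyte, muscle and pancreas markers, 7 had a log2 ratio of at least 1, and the median was 1.75, among them the fat hormone Adipoq at 9.55 against 0.448 FPKM. Of 12 squamous epithelium markers, 5 were at least 4-fold above NCC in FFC and 4 above every other pool, while 1 was above NCC in FFE. Among squamous genes keratin 13 (Krt13) stood at 21.7 and Krtdap at 28.3 FPKM in FFC against 0 in NCC. Hepatocyte markers had a median of -0.11.

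The effect of running on chow was read from the NCE and NCC pools. Cholesterol synthesis genes were higher with running, 23 of 24 with a positive ratio and a median of 0.43, and Sqle stood at 45.7 against 21.9 FPKM. Fatty acid and triglyceride synthesis had a median of 0.28, with Fasn at 172 against 61.7 and the desaturase Scd1 at 1101 against 463 FPKM. Genes of the unfolded protein response had a median of 0.38 and acute phase genes 0.35, the latter with Saa1 at 132 against 37.6 FPKM. Fatty acid oxidation had a median of -0.15 and clock genes -0.32, with the clock output gene Dbp at 23.4 against 42.7 FPKM and the core clock activator Arntl at 2.75 against 0.734. Macrophage markers had a median of -0.24. These medians lay at percentile 100, or at 0.03 or lower, among matched lists. Time of day at collection is not given for the pools, so it cannot be told apart from running in the clock genes or in the other lists of this comparison. Fat and muscle markers were higher here too, with a median of 1.29, and the brown fat gene Ucp1 stood at 7.51 against 1.19 FPKM. This comparison had the fewest genes at an absolute log2 ratio of at least 1 in the diet set, 181 of 11510, with 93 higher, 88 lower and 38 with bounds apart.

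The effect of running on fast food was read from the FFE and FFC pools, and acute phase and inflammatory genes were lower with running. All 23 acute phase genes had a negative ratio, with a median of -0.54, and Saa1 stood at 64.1 against 483, Saa2 at 13.7 against 154 and Lcn2 at 2.31 against 37.6 FPKM. Cytokines and chemokines had a median of -0.47, with Cxcl9 at 2.16 against 9.47 FPKM, and macrophage markers -0.28. All 24 cholesterol genes had a negative ratio, with a median of -0.23, and Sqle stood at 0.903 against 6.00 FPKM. Female-biased liver genes had a median of -0.79, with Cyp2b9 at 3.81 against 24.2 FPKM, and male-biased genes had 0.25. Lipid droplet genes had a median of 0.54, with Fabp4 at 1112 against 160 FPKM, and fatty acid and triglyceride synthesis had 0.24, with Fasn at 324 against 148.

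In this pool the largest ratios belonged to genes of other organs. Steroid-making genes of the adrenal gland led the list, with Hsd3b1 at 115 against 0.223, Star at 93.1 against 0.765 and Cyp11a1 (ENSMUSG00000032323) at 59.0 against 0.137 FPKM. The chromaffin granule proteins Chga and Chgb stood at 27.2 against 0.164 and at 26.1 against 0.079 FPKM. Muscle genes followed, with myoglobin (Mb) at 109 against 3.65 and creatine kinase (Ckm) at 50.4 against 2.01 FPKM, and the list of adipocyte, muscle and pancreas markers had a median of 2.49. The list of fibrosis markers, which holds Des, also a muscle gene, had a median of 0.41, and oncofetal genes had 0.77, with the imprinted RNA H19 at 20.7 against 0.927 and Dlk1, also made in the adrenal, at 7.95 against 0.0454 FPKM. In all 526 of 11996 genes had an absolute log2 ratio of at least 1, with 374 higher, 152 lower and 243 with bounds apart.

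**Figure D2:**
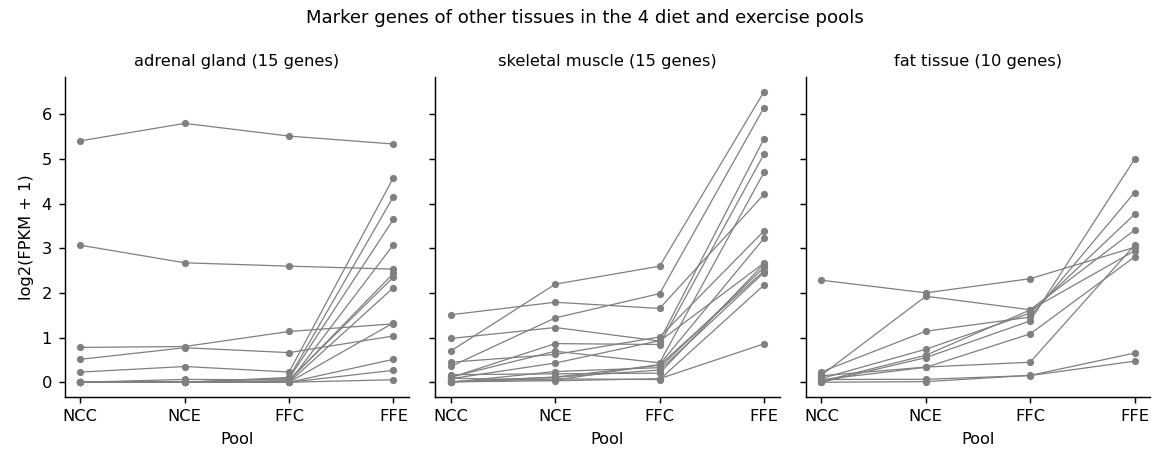
Expression as log2 of (FPKM + 1) (vertical axis) of 15 adrenal gland, 15 skeletal muscle and 10 fat markers in the 4 diet and exercise pools (horizontal axis), 1 pool per group and 1 point per gene. In FFE, 15 of 15 muscle markers and 9 of 15 adrenal markers are at least 4-fold above every other pool.

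The effect of diet among running mice, FFE against NCE, joined both sides of these shifts. Cholesterol genes had their lowest median of the diet set, -1.25, with all 24 negative, Sqle at 0.903 against 45.7 and Idi1 at 12.7 against 126 FPKM. Lipid droplet genes had a median of 1.32, lipogenic genes 0.89 and fatty acid oxidation 0.45, with Pdk4, which shifts fuel use from glucose to fat and is abundant in muscle, at 41.9 against 2.49 FPKM. Xenobiotic genes had a median of -0.90, with Cyp2b10 at 0.627 against 20.5 FPKM, unfolded protein response genes -0.57, acute phase genes -0.64 and one-carbon genes -0.32, the last with the methyl transferase Nnmt at 18.8 against 71.1 FPKM and Gnmt, which sets the supply of methyl donor, at 997 against 2108. In FFE, 15 of 15 skeletal muscle, 9 of 15 adrenal and 6 of 10 fat markers were at least 4-fold above every other pool. The lipid and oxidation lists thus moved beside markers of other tissues here too. Genes at an absolute log2 ratio of at least 1 numbered 627 of 11939, with 467 higher and 160 lower.

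Fast food and running together, FFE against NCC, gave medians of 1.09 for lipogenic genes, 1.42 for lipid droplet genes, -0.76 for cholesterol genes and -0.72 for xenobiotic genes. Elovl6 stood at 101 against 18.2, Fabp4 at 1112 against 21, Sqle at 0.903 against 21.9 and Cyp3a11 at 853 against 2593 FPKM. The adipocyte, muscle and pancreas list had its highest median here, 4.40, with the brown fat gene Ucp1 at 227 against 1.19 FPKM, so the lipid and oxidation lists moved beside markers of fat and muscle. Genes at an absolute log2 ratio of at least 1 numbered 649 of 11996, with 493 higher and 156 lower.

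The machinery of DNA methylation itself was near constant between the diet pools. No measured member of that list reached an absolute log2 ratio of 1 in any of the 5 diet and exercise comparisons, and its medians ran from -0.18 to 0.06. The maintenance methyltransferase Dnmt1 stood at 2.01 FPKM in NCC, 1.75 in NCE, 1.80 in FFC and 1.99 in FFE, and the de novo enzyme Dnmt3a at 3.04, 2.69, 2.75 and 2.64. The largest ratio was that of Mbd1, a reader of methylated DNA, at 8.89 FPKM in NCE against 15.1 in NCC.

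**Figure D3:**
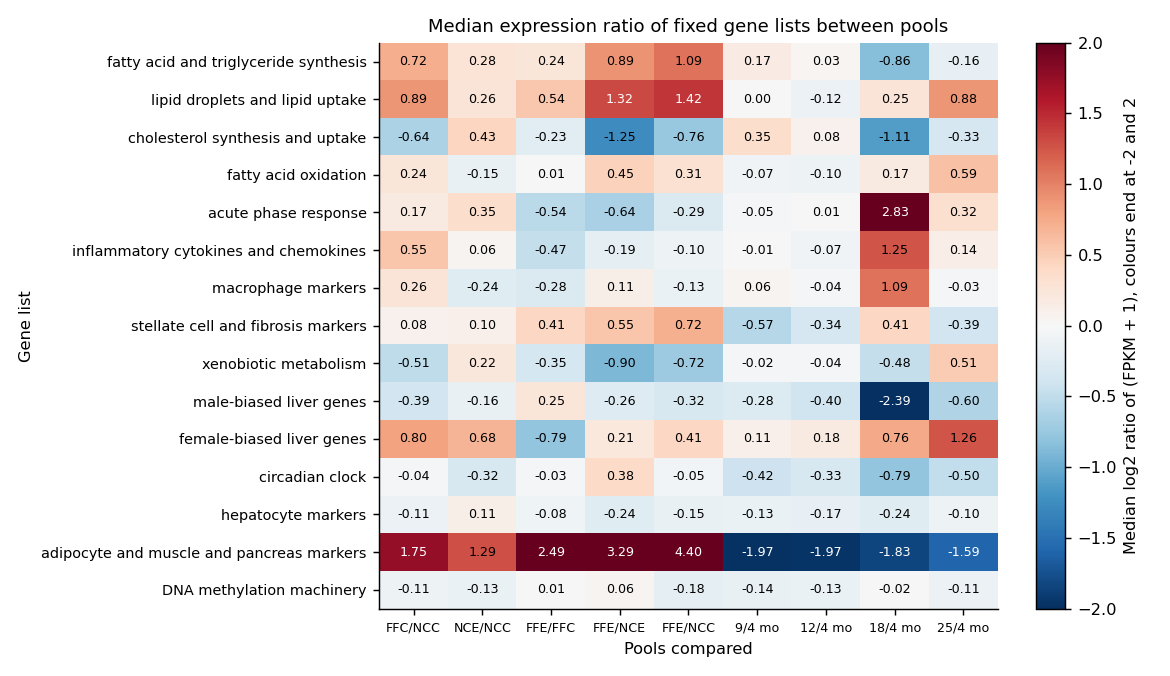
Median log2 ratio of (FPKM + 1) for 15 of the 30 gene lists fixed before the data were examined (vertical axis) in 9 comparisons of pools (horizontal axis), 1 pool per group; red is higher and blue lower, and colours end at -2 and 2. Cholesterol genes reach -1.25 for FFE against NCE, and acute phase genes 2.83 for 18 against 4 months.

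Very short features led some lists of extreme ratios because they stood at 0 in 1 of the 2 pools. The immunoglobulin segment Ighj4 was listed at 0 FPKM in NCC and at 59449 in FFC, with bounds that overlapped, and such features are not read as differences.

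Age was compared first at the level of all sites. Mean methylation of CpG islands rose with age, from 3.14% ± 0.0279 at 4 months (SD, n = 3) through 3.21% ± 0.0091 at 9 and 3.20% ± 0.0491 at 12 months to 3.37% ± 0.0055 at 18 months (n = 3 each) and 3.70% ± 0.161 at 25 months (n = 2). Over 263628 island sites in 14 libraries Pearson's r was 0.899 and Spearman's rho 0.900, with permutation p of 1e-05, the smallest the permutations can give, and 4e-05, and the adjusted p of r was 9e-05. Without the 2 libraries farthest from the median age, r was 0.895. At the 123953 other sites r was 0.106, with a permutation p of 0.717. The planned measure over all sites had r of 0.733 (permutation p = 0.0023, adjusted p = 0.0104) and rho of 0.591 (permutation p = 0.0279). It rested on the oldest livers, since without the 2 libraries farthest from the median age r was 0.398 (permutation p = 0.202), and with reads pooled over sites r was -0.513. The split by islands was added after seeing the data. Whether bisulfite conversion differed between the ages was not tested.

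Between 25 and 4 months 143 of 48042 tiles passed the test and the minimum difference of 10 points, 117 lower and 26 higher at 25 months. The balance depended on that minimum, since without it 144 tiles were lower, by a median of -22.2 points, and 685 higher, by a median of 2.27 points. Lower tiles lay almost entirely outside CpG islands, 1 of 117 being mostly island, and had a median difference of -24.3 points. Higher tiles lay mostly in islands, 16 of 26, and had a median of 13.2 points, against 38.4% island tiles among all tested. Island sites averaged 3.14% at 4 months, and a tile near that level could not fall by 10 points. Tiles were not matched on starting level, so the minimum difference limits this contrast. An intronic tile of Mtus2, a gene for a microtubule protein (mm9 chromosome 5, 148839001 to 148840000), fell from 81.2% ± 3.68 at 4 months to 28.2% ± 0.900 at 25 months (SD, n = 3 and 2; 28 to 287 reads per library). A tile 491 bp from the start of Parp3, a DNA repair enzyme, and upstream of Rrp9 (chromosome 9, 106378001 to 106379000) fell from 51.3% ± 4.75 to 9.77% ± 4.74. A tile within Rpusd1 and upstream of Chtf18, a gene of DNA replication (chromosome 17, 25867001 to 25868000), fell from 90.9% ± 0.590 to 51.1% ± 4.80, and an exonic tile of the mast cell tryptase Tpsab1 (chromosome 17, 25480001 to 25481000) from 81.1% ± 2.74 to 42.3% ± 2.21. A tile of Fitm1, which drives lipid droplet formation, and upstream of the proteasome gene Psme1 (chromosome 14, 56195001 to 56196000) fell from 75.0% ± 3.25 to 33.5% ± 8.74. Tiles of Wdr7, Wwox and 2210010C17Rik were also among the lowest, while those of Ptpn3 and Slc5a2 rested on 1 of the 2 oldest livers, with an SD of 35.3 and 41.1 points at 25 months.

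Regions that gained methylation included a tile of Alpk1, an innate immune kinase (chromosome 3, 127398001 to 127399000), which rose from 18.2% ± 2.26 to 55.1% ± 1.68, and an intronic tile of the phospholipid flippase Atp11a (chromosome 8, 12864001 to 12865000), from 52.2% ± 8.82 to 83.2% ± 2.92. Island tiles of the germ cell transcription factor Tcfl5, of Hhipl1, of 4933403G14Rik and of the ubiquitin ligase subunit Fbxl12 rose by 14.1 to 23.4 points. An island tile of the developmental regulator Hoxa5 (chromosome 6, 52153001 to 52154000) rose from 5.70% ± 1.76 to 17.5% ± 2.29, and a tile of Shmt2, a mitochondrial enzyme of one-carbon metabolism, fell from 89.9% ± 2.78 to 65.3% ± 4.28. The 10 highest also held tiles of Flrt1, Decr2, Zfp503 and Rltpr. Both 25 month libraries lay at least 10 points beyond the 4 month mean in 127 of the 143 tiles. That held for 112 of the 117 lower tiles but only 15 of the 26 higher tiles. The count depended on single libraries, being 20 without 25MO replicate 2 and 669 without 25MO replicate 1, and 75, 50 and 51 without 4MO replicates 1, 2 and 3. limma called 42 tiles and a fit of the 2 groups alone 59.

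Across all 5 ages, 302 tiles changed with age, 241 falling and 61 rising (341 and 1167 with no minimum difference), and 123 of them were also called between 25 and 4 months. Among tiles that fell, Cyp2f2, a liver cytochrome (chromosome 7, 27914001 to 27915000), went from 83.4% ± 3.21 at 4 months over 79.5% ± 4.24, 77.2% ± 2.84 and 61.1% ± 2.36 to 57.1% ± 6.13 at 25 months. Mtus2 stood at 73.7% at 12 months and 30.6% at 18 months. Nfic, a hepatocyte transcription factor, fell from 26.1% ± 1.64 to 8.08% ± 0.050, the inflammasome gene Nlrp6 from 20.6% ± 2.24 to 4.51% ± 0.170, and Ift140, a gene of cilia, from 92.4% ± 0.140 to 69.7% ± 6.04. Of the fixed list of fatty acid and triglyceride synthesis, a tile of Fasn fell from 67.4% ± 7.34 to 42.9% ± 0.840 at 25 months and a tile of Acly from 75.5% ± 4.97 to 58.0% ± 4.32. The liver regulator Hnf4a fell from 75.7% ± 8.73 to 59.2% ± 1.16 and the acute phase gene Saa4 from 82.2% ± 6.23 to 56.9% ± 21.7. Among tiles that rose, the promoter of Mrpl19 went from 0.05% ± 0.03 to 8.95% ± 1.70, and the receptor kinase Ptk7 from 7.48% ± 0.570 to 20.2% ± 2.93, the fatty acid transporter Slc27a3 from 7.90% ± 1.21 to 18.7% ± 0.490 and the demethylating enzyme Tet2, in an intron, from 12.4% ± 1.48 to 26.0% ± 7.20. The trend count was 171 without 25MO replicate 2, and limma called 94.

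**Figure D4:**
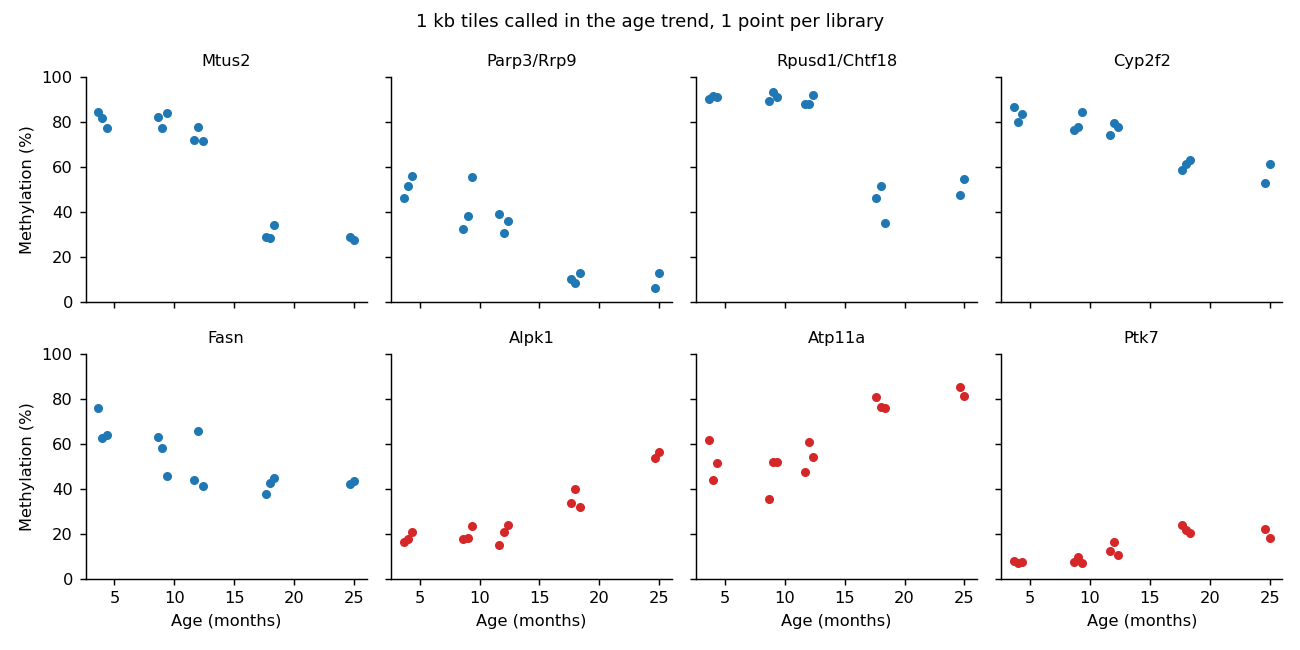
Methylation in percent (vertical axis) of 8 tiles of 1 kb against age in months (horizontal axis), 1 point per library; blue tiles fell with age and red tiles rose. Mtus2 stands between 73.7% and 81.2% on average up to 12 months and at 30.6% at 18 months.

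The change was concentrated between 12 and 18 months. For tiles called between 25 and 4 months, a median of 61.3% of the change fell in that step, against 13.1%, 3.6% and 18.3% in the steps from 4 to 9, 9 to 12 and 18 to 25 months. The 12 and 18 month groups do not enter the difference between 25 and 4 months, though their libraries add to the estimate of spread in the fit.

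No fixed gene list was enriched among called tiles in Fisher's exact test over gene-linked tiles, with the lowest adjusted p at 0.91 for the trend and 1.0 between 25 and 4 months over 30 lists. Hox genes held 2 called tiles of 137 in the trend, both rising, and fatty acid and triglyceride synthesis 2 of 70, both falling. Adjusted over the list alone, 9 tiles of the lists passed between 25 and 4 months and 17 in the trend, against 3 and 11 over all tiles.

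Expression at 25 against 4 months showed higher lipid oxidation, acute phase and DNA damage genes and lower male-biased genes. Fatty acid oxidation had a median log2 ratio of 0.59, with 22 of 25 positive, and the fatty acid hydroxylase Cyp4a14 stood at 956 against 160 FPKM. Lipid droplet genes had a median of 0.88, with Cidea (ENSMUSG00000024526) at 67.3 against 0.523 and Cidec at 47.9 against 5.85 FPKM. Acute phase genes had a median of 0.32, with Saa2 at 1162 against 28.6 and Lcn2 at 170 against 3.79 FPKM. Among genes of DNA damage and senescence, median 0.34, the cell cycle inhibitor Cdkn1a stood at 32.9 against 1.16 and Gdf15 at 18.5 against 3.76 FPKM. Xenobiotic genes had a median of 0.51, with Cyp2b10 at 69.8 against 11.8 FPKM, and female-biased liver genes 1.26, with Cyp2b9 at 12.6 against 0.120. Male-biased genes had a median of -0.60, with 17 of 18 negative, and Selenbp2 stood at 42.0 against 462 and Hsd3b5 at 31.4 against 171 FPKM. Clock genes went both ways, 8 of 19 positive and 11 negative, 5 and 8 of them at an absolute log2 ratio of at least 1. Their median was -0.50, with the output gene Dbp at 0.674 against 33.9 and the repressor Nr1d1 at 1.78 against 37.3 FPKM. Cholesterol genes had a median of -0.33. These medians lay at percentile 99.98 or higher, or at 0.0, among matched lists. Time of day at collection is not given for the pools, so it cannot be told apart from age in the clock genes or in the other lists of this comparison. Genes of the unfolded protein and amino acid stress response had a median of -0.17, at percentile 0.31, with 10 of 17 negative. Macrophage markers had a median of -0.03, lymphocyte markers -0.07 and hepatocyte markers -0.10. Other lists of cell markers lay further from 0, at -0.24 for endothelial markers (10 of 11 negative, percentile 0.29), -0.39 for fibrosis markers (13 of 16 negative, percentile 0.0), -0.33 for bile duct markers (4 of 5 negative, percentile 1.18) and 0.45 for blood cell markers (4 of 5 positive, percentile 99.73). In all 382 of 11838 genes had an absolute log2 ratio of at least 1, with 256 higher and 126 lower.

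The 18 month pool stood apart from the other ages in expression. Against 4 months 1100 of 12219 genes had an absolute log2 ratio of at least 1, compared with 185 at 9 and 196 at 12 months. Acute phase genes had a median of 2.83 over 18 genes, since the abundant Hp, Hpx, Fga, Fgb and Fgg had no usable estimate in this pool, with Saa2 at 12222 against 28.6, Saa1 at 12526 against 94.5 and Lcn2 at 1872 against 3.79 FPKM, and macrophage markers had 1.09, lymphocyte markers 0.84 and cytokines and chemokines 1.25. All 18 male-biased genes had a negative ratio, with a median of -2.39, and Hsd3b5 stood at 0.253 against 171 and carbonic anhydrase Car3 at 31.2 against 2392 FPKM. Cholesterol and lipogenic genes had medians of -1.11 and -0.86, with the lipogenic regulator Srebf1 at 10.6 against 68.0 FPKM. Igfbp1, a fasting and stress protein, stood at 959 against 14.9 FPKM. The comparisons of 9, 12 and 18 months were added after seeing the data.

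The DNA methylation machinery had a median of -0.11 at 25 months and -0.02 at 18 months, with no member at an absolute log2 ratio of 1. Dnmt1 stood at 2.02 and 2.32 FPKM at 25 and 4 months, Dnmt3a at 3.4 and 3.95 and Tet3 at 1.90 and 2.58.

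Methylation and expression differences were compared across genes, which are not independent replicates. Spearman's rho was small throughout, at -0.0559 for running on fast food, -0.0866 for diet in running mice and -0.0536 for diet and running together, with permutation p adjusted over 6 comparisons of 3e-05, 3e-05 and 4e-05. These 3 comparisons share the FFE pool, in which muscle, adrenal and fat markers were higher, and the other 2 of the diet set did not pass. The coefficient was -0.0186 for diet in sedentary mice (adjusted p = 0.162), -0.0068 for running on chow (adjusted p = 0.586) and 0.0431 for 25 against 4 months (adjusted p = 4.5e-05). With at least 50 reads per tile the last was 0.0205, with a permutation p of 0.054. Of the genes linked to tiles that fell between 25 and 4 months, 76 were measured in the pools, with a median log2 ratio of -0.09, and 4 had an absolute ratio of at least 1. The 9 genes linked to tiles that rose had a median of -0.03, and 0 of them did.

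Whether calls for diet recur with age could not be asked as planned, since diet and running gave no calls, so calls between 25 and 4 months were used. Of 25 such tiles measured in the diet set, 36.0% differed in the same direction in fast food against chow livers and 64.0% in running against sedentary livers. Random tiles matched on level averaged 54.6% and 52.8%, with two-sided p of 0.0925 and 0.358 from 10000 random tile sets and adjusted p of 0.154 and 0.488.

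Livers of the beta-catenin transgenic mouse and of DEN-treated mice, models of liver tumour formation, had 1 library each and no control of their own. Beta-catenin is the effector of Wnt signalling, and DEN is read here as the liver carcinogen diethylnitrosamine, which the labels do not spell out. Many regions lay below all age livers. Of 44338 tiles, 1122 lay at least 25 points below the range of the 14 age libraries in beta-cat_TG, 449 in beta-cat_TG+DEN and 855 in DEN, while 132, 74 and 172 lay above it. Each age library held against the other 13 gave 0 to 31 such tiles. Afp, the fetal liver gene re-expressed in liver tumours, had an exonic tile at 18.0% of 1318 reads in beta-cat_TG (Wilson 95% interval 16.0% to 20.1%), against 57.3% to 78.5% in age livers. A tile upstream of the cyclin gene Ccna2 (chromosome 3, 36471001) stood at 59.4% in beta-cat_TG (interval 47.1% to 70.5%, 64 reads) and 44.8% in beta-cat_TG+DEN (38.6% to 51.1%, 239 reads), against 0.0% in all age livers and 5.7% in DEN (3.1% to 10.2%, 175 reads). A tile upstream of the plasma inhibitor Pzp, chosen after its values were seen, stood at 18.2% (9.5% to 32.0%, 44 reads) and 9.5% (4.7% to 18.3%, 74 reads) in the transgenic livers, against 83.5% to 93.2% with age. A tile of Dnmt1 stood at 45.8% (35.5% to 56.4%), 50% (40.5% to 59.5%) and 33.6% (25.7% to 42.6%) in the 3 libraries, against 78.5% to 98.6%. These intervals cover counting error only. In beta-cat_TG 1 of 28 tiles of the oncofetal list, which holds Afp, lay below the age range where its overall rate gives 0.53, 1 of 51 tiles of the DNA methylation machinery did where it gives 0.97, and 1 of 39 tiles of the proliferation list, which holds Ccna2, lay above where it gives 0.11.

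These 3 libraries list each strand apart, as the diet set does and the age set does not. Strain and age are not given for the transgenic mice, so a difference in age from the 9 month livers cannot be told apart in the shares below. The mean methylation of the 3 libraries over the tiles was 31.0%, 33.0% and 32.9%, against 36.4% to 37.3% in age livers. On 15240 tiles covered in all libraries, they had 119, 54 and 98 tiles outside the age range. The 12 diet livers, which share that format, had 31 to 614. On the same tiles the mean methylation of the 3 libraries was 14.23%, 14.99% and 15.11%. The diet livers had means from 14.2% to 15.79% and the age livers from 16.2% to 16.64%. All 12 diet livers thus also lay below the age livers, so a lower mean was not particular to the 3 libraries. Of 133 tiles called between 25 and 4 months, 80.5% differed in the same direction in beta-cat_TG+DEN and 78.9% in DEN relative to 9 month livers, against 67.0% and 67.4% for random tiles matched on level and direction (two-sided p of 0.0005 and 0.0027 over 10000 random tile sets, adjusted p of 0.00675 and 0.0101 over 15 shares). In beta-cat_TG the share was 78.9%, against 72.5% for random tiles (two-sided p of 0.0813 over 10000 random tile sets, adjusted p of 0.154). All p-values of these shares treat tiles as independent and come from 1 library each, so they measure no spread between animals. Higher and lower tiles were also compared apart, and whether libraries differed in this was not tested. In beta-cat_TG 75.0% of the 24 tiles higher at 25 months went the same way, against 42.4% of random tiles (adjusted p = 0.0101), and 79.8% of the 109 lower tiles did, against 79.2% (adjusted p = 0.965). In beta-cat_TG+DEN the shares were 54.2% against 40.2% for higher tiles (adjusted p = 0.363) and 86.2% against 72.7% for lower tiles (adjusted p = 0.00675), and in DEN 70.8% against 48.9% (adjusted p = 0.103) and 80.7% against 71.5% (adjusted p = 0.0933). With 12 month livers as reference, the adjusted p of lower tiles in beta-cat_TG+DEN was 0.112 and of all tiles there 0.0979.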

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

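The test of fetal liver markers, the test of bisulfite conversion, the weighing of leukocyte tiles against marker RNA and the counts over other splits of the libraries were chosen only after the results were seen.

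Running was associated with opposite shifts on the 2 diets in 9 gene lists, each read from 1 pool per group and not tested. In these the median of both comparisons lay outside the middle 95% of matched random lists and on opposite sides of 0. The genes measured on the 2 diets were not all the same. All 9 medians on fast food use the FFE pool. In that pool 15 of 15 skeletal muscle, 9 of 15 adrenal and 6 of 10 fat markers were at least 4-fold above every other pool. Other tissue in the pool therefore cannot be told apart from running in any of these lists. Acute phase genes had a median log2 ratio of 0.35 with running on chow and -0.54 on fast food, a difference of -0.89. Female-biased liver genes had 0.68 over 6 genes and -0.79 over 9, a difference of -1.47, and over the 5 genes in both 0.63 and -0.79. Blood cell markers had 0.32 and -0.30, a difference of -0.62, with 2 of 5 positive on fast food. Oncofetal genes had -0.33 over 5 genes and 0.77 over 9, a difference of 1.1, and over the 5 genes in both -0.33 and 0.75, where the second comes from the FFE pool, which also held adrenal transcripts. Cholesterol synthesis genes had 0.43 and -0.23, a difference of -0.66, genes of the unfolded protein response 0.38 and -0.22, a difference of -0.61, and xenobiotic genes 0.22 and -0.35, a difference of -0.57. One-carbon genes had 0.16 and -0.23, a difference of -0.39, and male-biased liver genes -0.16 and 0.25, a difference of 0.4. Over the 17 male-biased genes in both, the medians were -0.10 and 0.25. Of the genes in both comparisons, 3 of 5 differed in sign in each of the female-biased, oncofetal and blood cell lists. This tally was 23 of 24 for cholesterol, 18 of 23 for acute phase and 12 of 17 for unfolded protein response genes. It was 14 of 19 for xenobiotic, 17 of 22 for one-carbon and 14 of 17 for male-biased genes.

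The FFE pool held transcripts of adrenal gland, muscle and fat. Fetal-type expression was set against tissue carried into the pool, and 28.6% of 7 fetal liver markers were at least 4-fold above NCC and 0% above every other pool, with Afp at 0.144 against 0.267 FPKM, which leaves it open. Of markers not looked at before, 60% for adrenal gland and 100% for skeletal muscle were at least 4-fold above every other pool and 80% for fat were so above NCC, with Akr1b7 at 23.0 FPKM and Mylpf at 90.2, though the adrenal markers Mrap and Syt1 were in other pools too, so tissue from outside the liver may be part of this pool. A bound was set in advance against fat as the whole source of the higher lipid droplet genes in FFC. It asked for more than 60% of them above the highest fat marker in the ratio of FFC to FFE excess over NCC. With 42.9%, or 6 of 14, it was not met, so for the set fat cannot be told apart from a change in liver. For those 6 genes, Plin2 (0.728) and Cd36 (0.647) among them, the excess was more than the fat markers (at most 0.308) would bring. Fabp4 and Cidea were not above them, and each value rests on 1 pool per group. An effect of running on the liver itself was not tested for these genes.

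For tiles called between 25 and 4 months, a median of 61.3% of the change fell between 12 and 18 months. Leukocytes in old livers remain open. All 19 measured macrophage markers (median log2 ratio 1.09) and all 10 lymphocyte markers (0.84) were higher in the 18 month pool than at 4 months, while at 25 months the medians were -0.03 and -0.07. Tiles of leukocyte genes had a median difference of -1.46 points (bootstrap 95% interval -3.69 to 0.93), which was set in advance to speak against leukocytes, but that bound was wrong to treat 15 tiles as independent and to take them as unmethylated in leukocytes, of which no library exists here. Strain variants remain open too, with 128 of the 143 calls left without sites at known variants, and 50% of the 322 calls of both age comparisons near another, against 43.7% of random tiles. A difference between the mice or libraries up to 12 months and the older ones cannot be told apart from age, which stays untested. From 9 to 12 months 59.4% of calls went the called way (95% interval 50.9% to 67.6%), which was set in advance to speak against it, but that bound was wrong to treat tiles as independent, since 4 of 20 splits of those 6 libraries gave as high a share and the highest other was 63.6%.

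Mean methylation was lower in fast food livers. Incomplete bisulfite conversion as the whole source was argued against, since the fall outside islands exceeded that in islands by a difference of -0.703 points, also without each of the 12 libraries. This comparison cannot exclude that conversion gave a part of the fall, since islands fell too. Sequencing depth remains open, with r of 0.297 between log reads and mean methylation within groups (permutation p = 0.524). DNA of cells other than hepatocytes also remains open, since hepatocyte gene tiles differed by 0.542 points (95% interval -0.005 to 0.985). An effect of diet is a hypothesis these tests leave standing beside them.

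For the tile counts, 3 against 3 libraries make 10 splits, too few for a share under 0.05. In these 5 comparisons the real count was 0 and the highest other split gave 0 or 1. For both averages and the interaction the real count was also 0, which all 40 of 40 splits reach by necessity, and the highest other was 0, so these splits say nothing about chance. For the age trend only the real order of ages, 1 of 40 splits, gave as many as 302 tiles, and the highest other gave 1. That is the smallest share 40 splits can give. These splits argue against a random order of libraries as the source, but cannot separate age from a difference between mice or libraries.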

How the results depend on the processing

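Among the alternatives, leaving out variant sites, keeping only sites covered in every library, leaving out the libraries that stood apart, and the comparisons of 9 and 12 months were chosen only after the results were seen. The cause of the changes given here was not tested unless stated. Depth limits the diet set most, where the shallowest library had 3877081 CpG reads, and the depth of the pools is unknown.

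Tiles for diet and exercise stayed at 0 calls in 101 settings, counted per comparison, apart from those that left out 1 library. These include fits of only the groups compared and fits without the libraries that stood apart. Leaving out 1 library, with the highest count always without NCC replicate 1, gave 0 to 13 tiles for diet in sedentary mice, 0 to 10 for running on chow, 0 to 20 for diet and running together and 0 to 2 for running averaged over diet, and 0 in the other 4 comparisons. Between 25 and 4 months the count was 829 with no minimum difference, 89 at 20 points, 42 by limma, 57 with coverage thinned, 306 with sites covered in every library, 59 with only the groups compared, and 20 to 669 without 1 library, the lowest without 25MO replicate 2 and the highest without 25MO replicate 1, where 25MO with 1 library left is assumed to vary like the other groups. For the age trend it was 1508, 174, 94, 164 and 470 under the first 5 of these and 171 to 331 without 1 library, the lowest without 25MO replicate 2. In 12 other settings the age counts stayed within 1.5 times.

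Mean methylation gave -2.32 points for diet with reads pooled (exact permutation p = 0.23), and -0.673 to -0.483 without 1 library. For running it gave -0.411 at 20 reads per site (exact permutation p = 0.015), -3.80 with reads pooled (exact permutation p = 0.03) and -0.391 to -0.201 without 1 library, with 4 of these past the threshold, without NCC, NCE or FFC replicate 2 or FFE replicate 1. For age, r was -0.513 with reads pooled, the reverse of the main value, 0.398 without the 2 libraries farthest from the median age, and 0.622 to 0.805 without 1 library.

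With a replicate block, which treats equal replicate numbers as paired, the counts were 102 between 25 and 4 months and 217 for the trend, 0 in all 8 diet and exercise comparisons, and -0.597 points for diet (exact permutation p = 0.0313). The numbers do not appear to pair libraries, since residuals of those with the same number had a median r of -0.002 over 18 pairs in the diet set and 0.005 over 26 pairs in the age set.

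Counts of genes at an absolute log2 ratio of at least 1 with a pseudocount of 0.1 were 535 for diet in sedentary mice, 356 for running on chow, 858 for running on fast food, 991 for diet in running mice, 1012 for both together, and 609, 345 and 346 at 25, 9 and 12 months. With genes of at least 5 FPKM, fewer of which were tested, the first 5 were 200, 115, 280, 360 and 352. In 32 other settings counts stayed within 1.5 times. Tiles outside the age range were 3904 in beta-cat_TG, 1803 in beta-cat_TG+DEN and 2995 in DEN at 15 points, and 721, 250 and 532 at 50 reads. The Spearman correlation of methylation and expression differences with age was 0.0205 at 50 reads (permutation p = 0.054), and 11 other settings kept their side of the threshold. With 12 month livers as reference, the 3 shares of age calls in the single libraries did too by unadjusted p, but in beta-cat_TG+DEN the adjusted p was 0.0979, and 0.112 for lower tiles.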

Other observations

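The tests of small differences with age, over tiles and over genes, and of the squamous markers were chosen only after the results were seen.

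Small gains of methylation in CpG islands went beyond the tiles called above. With no minimum difference, 1167 tiles rose in the age trend, 85.9% of them mostly island, by a median of 1.87 points from a level of 0.69% at 4 months, and 341 fell. Bisulfite conversion was not tested as a source of these small gains. Among gene-linked island tiles, 5 of 14 tiles of lipid droplet and lipid uptake genes rose, in Lpl, Pparg and Vldlr, which handle fat uptake and storage, against 5.3% of others (Fisher's exact test, two-sided, p = 0.00058, adjusted p = 0.0174 over 30 lists). This did not hold over both comparisons and directions (adjusted p = 0.0696 over 120 tests), nor over genes, since tiles of 1 gene are not independent, with 3 of 9 genes against 7.0% of others (Fisher's exact test, two-sided, p = 0.0213, adjusted p = 0.32 over 30 lists). Between 25 and 4 months 3 of 14 tiles did (adjusted p = 0.291), and Hox genes had 5 of 68 in the trend (adjusted p = 1.0).

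Fat and muscle markers had medians of -1.97, -1.97, -1.83 and -1.59 at 9, 12, 18 and 25 months against 4 months, over only 3 measured genes, of which 1 was higher at 9 and at 12 months. Fibrosis markers, which hold collagens, had medians of -0.57, -0.34 and -0.39 at 9, 12 and 25 months and 0.41 at 18 months. Squamous markers were at least 4-fold above NCC in 41.7% of 12 genes in FFC, with Krt4 at 11.4 FPKM. The female transcript Xist was at most 0.044 FPKM in all pools, and Eif2s3y, from the Y chromosome, was at least 29.1 FPKM.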
